A study of Mus musculus with 33 samples.

How the data were processed

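Midbrain RNA of male C57Bl/6 mice aged 8 weeks was compared on in-house printed 2-colour oligonucleotide arrays. One channel held RNA from mice that had received 1000000 LL/2(LLC1) cells, a mouse lung carcinoma line, under the skin in 300 µl PBS, and the other held RNA from mice injected with PBS. The labels gave 4 biological replicates at 18 h, 4 at 72 h and 6 at 192 h after injection. These were spread over 33 arrays of 4 layouts, with repeat arrays of a replicate in the opposite dye orientation where 2 orientations existed. Replicates 1 and 2 of each time were poly(A) RNA (17 arrays) and the others total RNA (16 arrays), per the labels. RNA type changed together with the array layout, and each type held all 3 times. Total RNA was on layout 4 alone. Within poly(A) RNA the layout also differed between times: 1 and 3 at 18 h, 1 at 72 h, and 2 and 3 at 192 h.

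The deposited scanner files (111 files, 3 per array and 6 for 4 arrays) gave a linear intensity per spot and channel with the background already taken off, per the file headers. They also gave the local background intensity and, per the file headers, the fraction of a spot's pixels that were not saturated. Software, scanner and gain are not given in the sources used here. The authors also deposited log2 values per spot. Their medians per array lay between -0.019 and 0.0049, so they were centred. They correlated with the scanner ratio of channel B over channel A at r = 0.39 to 0.81 where the tumour RNA was in Cy5 and at r = -0.77 to -0.35 where it was in Cy3, across spots, so the sign had been turned on swapped arrays. Their SD per array (median 0.23) was below that of the ratios computed here (median 0.49), and the smoothing or scaling behind this stays unknown. No label or header says which scanner channel held which dye. The direction tumour over PBS is therefore called likely, on the basis that channel B moves with the authors' values as Cy5 would.

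Log2 ratios were computed per scanner file and normalized within the array by global loess. Files of an array were averaged per spot over those in which the spot was not saturated, or over the least saturated where all were. Spots rejected by the scanner software or without signal above 0 in both channels were left out, and so were spots under 1 SD of the local background in both channels. The plan did not say over what that SD was taken, and after the files were seen it was taken over the spots of a scanner file. The plan fixed before the data were examined named normexp with an offset of 50. The intensities turned out to be background-corrected already, so no further correction was made and normexp became an alternative. For the 4 arrays with 6 files, log2 ratios of the further files correlated with those of the first 3 at r = 0.54 to 0.88 across spots, against 0.74 to 0.95 among the first 3. They were treated as further scans. All 4 arrays belonged to poly(A) RNA replicates 1 and 2 of 72 h.

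Ratios were averaged over spots of a probe, probes of a gene, arrays of an orientation and then the orientations of a replicate with equal weight. A spot therefore kept its dye effect where it was measured in 1 orientation only. Probe names came from a supplied table with 9086 probes for layouts 1 and 2 and 9078 for layouts 3 and 4. Of these, 9074 and 9066 had 1 symbol, 12 had several and were not named, and 8985 and 8977 were found by gene ID in the supplied mouse gene table, which changed 0 symbols. For layouts 1 and 2 the table's order did not match the arrays. Brightness per probe correlated with layouts 3 and 4 at a Spearman rho of 0.11 and 0.057 for layout 1 and 0.033 and 0.052 for layout 2 as supplied. After reordering by the printing plates these became 0.55 and 0.45, and 0.52 and 0.54, against 0.53 between layouts 3 and 4 (across 9008 probes). The correlation of duplicate spots went from -0.034 to 0.30 on layout 1 and from 0.10 to 0.20 on layout 2 (55 pairs). The reordered names were used for these 14 arrays. This was chosen after the data were seen, from brightness and not from the ratios. Ratios were obtained for 8726 genes, 263 of them with several probes.

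Genes with a value in at least 3 replicates of each time (6426) were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, jsonlite 2.0.0), with 1 coefficient per time tested against 0, a moderated F test of the differences between times, and Benjamini-Hochberg adjusted p under 0.05. Lists of genes (28, fixed before the data were examined) were tested with cameraPR at an inter-gene correlation of 0.01 where at least 5 members were tested, which left 25. The serotonergic, forebrain and antigen-presentation lists had 3, 4 and 0 members tested. The camera p takes genes as its units and does not measure the spread of a list mean between replicates. While the list members were being matched, a wrong synonym was found to have put 1 gene into the hypothalamic list, and the same rule affected the blood cell list. The matching was corrected after its value had been seen, which moved that list's unadjusted p at 72 h from under 0.05 to 0.069. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

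By the naming rule fixed before the data were examined, fewer than 10 calls at a time meant that the 10 genes of smallest p with the same sign in every replicate that measured them were named, with the 6 genes of smallest adjusted p for the differences and up to 4 members of each list described. Unnamed clones were passed over. The agreement in sign of these 10 genes follows from the rule and is no support for them. Of the 6426 genes, 1044 at 18 h, 1194 at 72 h and 567 at 192 h had 1 sign in every replicate that measured them. Which lists to describe was set after the values were seen: those with an unadjusted p under 0.1, at most 4 per time.

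Alternatives covered the background, the normalization, the dim-spot filter, the repeat scans, the authors' values, the dye term, RNA type, weights, each replicate left out, the replicate number and other set tests. A further 6 were added after the data were seen: normexp, the names as supplied, arrays named as supplied, values measured in both orientations, leaving out the 2 replicates of widest spread, and the first 3 files alone. On simulated data of 6426 genes, with the dyes taken as exchanged, the fit recovered 38.8% of 1.5-fold and 89.6% of 2-fold changes at 18 h, 40.3% and 80.6% at 72 h, and 55.2% and 95.5% at 192 h. The simulated noise was independent and normal, with 1 SD per gene for all replicates and no dye effect. In the real replicates the SD of the log2 ratios ran from 0.26 to 0.95. The recovery therefore holds for the simulated setting and may differ in the real data. The number of arrays limits the precision. The median SE of a gene's log2 ratio was 0.15 at 18 h, 0.15 at 72 h and 0.14 at 192 h. Each SE given with a gene is the moderated SE of the fit. Its spread is shared over the 3 times and drawn towards that of the other genes. It is thus not the SE of that time's replicates alone, which varied more for some genes.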

Results

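Gene expression in the midbrain of mice carrying a subcutaneous lung carcinoma was compared with that of PBS-injected mice at 18, 72 and 192 h, with 4, 4 and 6 biological replicates. The comparison asks which midbrain transcripts differ after tumour cell injection and whether that changes with time. An array gave a ratio for 1354 to 9266 spots (median 5826), and 33.0% of spots on the median array had signal in 1 channel only in the second scan. The median signal in that scan was 1.69 times the local background in one channel and 2.49 times in the other. All ratios are tumour over PBS on the log2 scale, a direction that is likely rather than stated, because the channel holding Cy5 was inferred from the authors' values.

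At 18 h the smallest p belonged to Noxo1, the organizer subunit of NADPH oxidase, with a log2 ratio of 0.53 ± 0.10 (SE, n = 4). It was higher in 4 of 4 replicates, as the naming rule required. Pms2, a mismatch repair gene, stood at 0.59 ± 0.12 (SE, n = 4) and Dcun1d1, which acts in cullin neddylation, at 0.51 ± 0.12 (SE, n = 4). Ifna4, an interferon alpha gene, stood at -0.64 ± 0.15 (SE, n = 4) and Id1, an inhibitor of basic helix-loop-helix factors, at -0.49 ± 0.12 (SE, n = 4). Otub2 and Fam184a were at 0.63 and 0.60, Aff2 at 0.38, Cops7b at -0.54 and Peg12 at -0.46. With print-tip loess Cops7b was at -0.075, Aff2 at 0.083, Otub2 at 0.24, Noxo1 and Pms2 at 0.27, Peg12 at -0.27 and Ifna4 at -0.38. None of these passed the test (adjusted p = 0.77 for each in limma). Of 6426 genes, 0 passed in limma, while 347 had an unadjusted p under 0.05, 206 higher and 141 lower, where chance gives 321. With print-tip loess that count was 202.

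Among the gene lists, the 10 cerebellar neuron genes had the smallest p at 18 h (camera p = 0.023, adjusted p = 0.57). Their mean log2 ratio was -0.12, with an SE of the replicate means of 0.12, and 8 members were lower. The leading members were Pcp4 at -0.37, Pcp2 at -0.27, Zic1 at 0.23 and Cbln3 at -0.22. Pcp4 was at 0.030 in the total RNA replicates alone, and with print-tip loess Pcp4 was at -0.011 and Zic1 at 0.068. In this list 0 members were past the test when adjusted over the list alone. Of the 25 lists tested, 0 passed at 18 h in cameraPR and 1 had an unadjusted p under 0.05. Without 18 h replicate 3 the cerebellar list passed over 9 members (mean -0.21, adjusted p = 0.041), and without 18 h replicate 2 its mean was -0.028. With median centring in place of loess the ribosomal protein genes passed (mean 0.15). Irf7, an interferon regulatory factor, was the 1 gene of any list at 18 h that passed when adjusted over the list alone (log2 ratio -0.63 ± 0.18, SE, n = 3, adjusted p = 0.033 in limma). Irf7 is named here after its value was seen. An adjustment over 1 list alone does not cover the other lists and times, so some such calls can come by chance.

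At 72 h, Foxo3, a forkhead transcription factor, had the smallest p, with a log2 ratio of -0.81 ± 0.16 (SE, n = 4). It was lower in 4 of 4 replicates, as the naming rule required. Skida1 stood at -1.07 ± 0.21 (SE, n = 4), the heat shock factor Hsf2 at -0.89 ± 0.21 (SE, n = 4) and the zinc finger repressor Zbtb18 at -0.63 ± 0.15 (SE, n = 4). The SD over the 72 h replicates was 0.70 for Skida1, 0.75 for Hsf2, 0.31 for Zbtb18 and 0.34 for Foxo3. Lrrc27, Tmem53, Tpst1, Tex37 and Cks2 were at -0.95, -0.70, -0.60, -0.51 and -0.37, and Washc1, of the WASH actin-regulating complex, was at 0.46. In the poly(A) RNA replicates alone Hsf2 and Lrrc27 were at -1.52 and -1.71 and passed, against -0.27 and -0.18 in total RNA. In the authors' processed values Tmem53, Tpst1 and Zbtb18 were at 0.017, 0.028 and 0.054, and with only the second scan Tmem53 was at 0.14. In all replicates none passed (adjusted p = 0.43 for each in limma). Across the 6426 genes 0 passed in limma, with 596 at an unadjusted p under 0.05, 210 higher and 386 lower. With only the first 3 scanner files of the 4 arrays that had 6, that count was 377 of 6218 genes. From the poly(A) RNA replicates alone 122 genes passed at 72 h, among them Hsf2 and Lrrc27, and from the total RNA replicates alone 0. The 122 became 17 with only the first 3 scanner files and 9 with only the second scan, 15 of the 17 and 5 of the 9 being among the 122.

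Heat-shock and chaperone genes had the smallest list p at 72 h, with a mean of 0.067 and 27 of 40 members higher (camera p = 0.035, adjusted p = 0.32). Its leading members were Hsf2 at -0.89, Dnajc8 at 0.54, Hsp90b1 at 0.52 and Hspa4 at 0.35. Without 72 h replicate 2 the list mean was 0.019, Dnajc8 was at 0.28 and Hsp90b1 at 0.14. In the authors' processed values the mean of the heat-shock and chaperone genes at 72 h was 0.0056, and Dnajc8 at 72 h was at 0.13 with only the second scan and 0.23 with print-tip loess. The 8 microglia and macrophage genes had a mean of 0.12 (camera p = 0.047, adjusted p = 0.32), from Aif1 at 0.43, Cd68 at 0.31 and C1qc at 0.21, while Laptm5 stood at -0.47. With print-tip loess this mean was 0.054. Without 72 h replicate 1, 2 or 4 it was 0.20, 0.15 or 0.21. Laptm5 had no value in 72 h replicate 3, so it was not tested in any of these 3 fits. Their means therefore leave out this lower member, and a rise from 0.12 does not show a stronger shift. With only the second scan Cd68 was at 0.021 and Laptm5 at -0.17, and in the authors' processed values Aif1 was at 0.018. Oxidative phosphorylation genes had a mean of 0.046, with 41 of 58 members higher (camera p = 0.057), led by Atp5j2 at 0.49, Ndufs4 at 0.29, Ndufa10 at -0.62 and Ndufaf3 at 0.23. Hypothalamic genes had a mean of -0.13 over 6 members (camera p = 0.069), with the peptide genes Oxt at -0.49, Pmch at -0.55 and Gnrh1 at -0.43, and Hcrt at 0.81. The hypothalamic mean was -0.25 with median centring. It was -0.046 without 18 h replicate 2, where Pmch had too few values left to be tested. Without 72 h replicate 3 it was -0.40, with Hcrt no longer tested for the same reason. Leaving out 192 h replicate 6 also lost Hcrt, and the mean at 72 h was then -0.32. These left-out means thus changed at least partly through the members lost. The SE of the replicate means was 0.045 for the heat-shock, 0.048 for the microglia, 0.055 for the oxidative phosphorylation and 0.067 for the hypothalamic list. In cameraPR 0 of 25 lists passed at 72 h, and 2 had an unadjusted p under 0.05. Adjusted over the list alone, and so not over the other lists and times, Hsf2 passed in the heat-shock list and Aif1 and Laptm5 in the microglia list. The mean of the oxidative phosphorylation genes was -0.011 in the total RNA replicates alone and -0.016 without 72 h replicate 2, and Hsp90b1 was at -0.041 in total RNA. Ndufa10 was at -2.37 in replicate 1 against -0.16 to 0.049 in the others, and at 0.026 in total RNA, 0.056 with only the second scan and 0.0052 in the authors' processed values.

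At 192 h the smallest p belonged to Cyb5r1, a cytochrome b5 reductase gene, with a log2 ratio of -0.47 ± 0.10 (SE, n = 5). It was lower in 5 of 5 replicates that measured it, as the naming rule required, and at -0.14 with only the second scan. Bmp2, a bone morphogenetic protein, stood at 0.42 ± 0.10 (SE, n = 5) and Cntn3, a neural adhesion molecule, at -1.43 ± 0.39 (SE, n = 6). The SD over the 192 h replicates was 1.47 for Cntn3, 0.25 for Bmp2 and 0.17 for Cyb5r1. Vsir, an immune checkpoint gene, was at 0.34 and the splicing factor gene Srsf10 at 0.50, with Arhgap24 at -0.58, Iws1 at -0.36, Sox7 at -0.32, the ephrin receptor gene Epha3 at -0.48 and Bhlha15 at -0.41. With median centring in place of loess Sox7 was at 0.11. None passed (adjusted p = 0.96 for each in limma). Over all 6426 genes 0 passed in limma, and 253 had an unadjusted p under 0.05, 110 higher and 143 lower.

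Acute-phase and inflammatory genes had the smallest list p at 192 h (camera p = 0.018, adjusted p = 0.46). Their mean was -0.17, with an SE of the replicate means of 0.22, and 7 of 10 members were lower. Members were Ccl4 at -0.63, Lcn2 at -0.20, Il1b at -0.18 and Il6 at -0.18, which in the authors' processed values were at 0.15, 0.015, 0.048 and 0.057. In the total RNA replicates alone this list passed (mean -0.32, adjusted p = 0.039). Replicate 4, of total RNA, had a list mean of -1.36, against -0.25 to 0.13 in the other replicates. Without 192 h replicates 4 and 6, 0 lists at 192 h had an unadjusted p under 0.05. The mean of the acute-phase genes was -0.097 without replicate 4, 0.0068 in the authors' processed values and 0.0062 in the poly(A) RNA replicates alone. With median centring in place of loess 4 lists passed at 192 h, this one among them. Proteasome subunit genes had a mean of 0.018 (SE of the replicate means 0.075), with 14 of 20 members higher (camera p = 0.062). They were led by Psmd3 at 0.31, Psma6 at 0.28, Psmb2 at 0.18 and Psmb3 at -0.85, which was -5.07 in replicate 6 and 0.00033 without it. The proteasome mean was -0.012 without replicate 4, -0.0089 without replicate 5, -0.0074 with array weights and -0.0012 without background subtraction. In cameraPR 0 of 25 lists passed at 192 h, 1 had an unadjusted p under 0.05, and 0 members of any list passed when adjusted over the list alone.

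**Figure D1:**
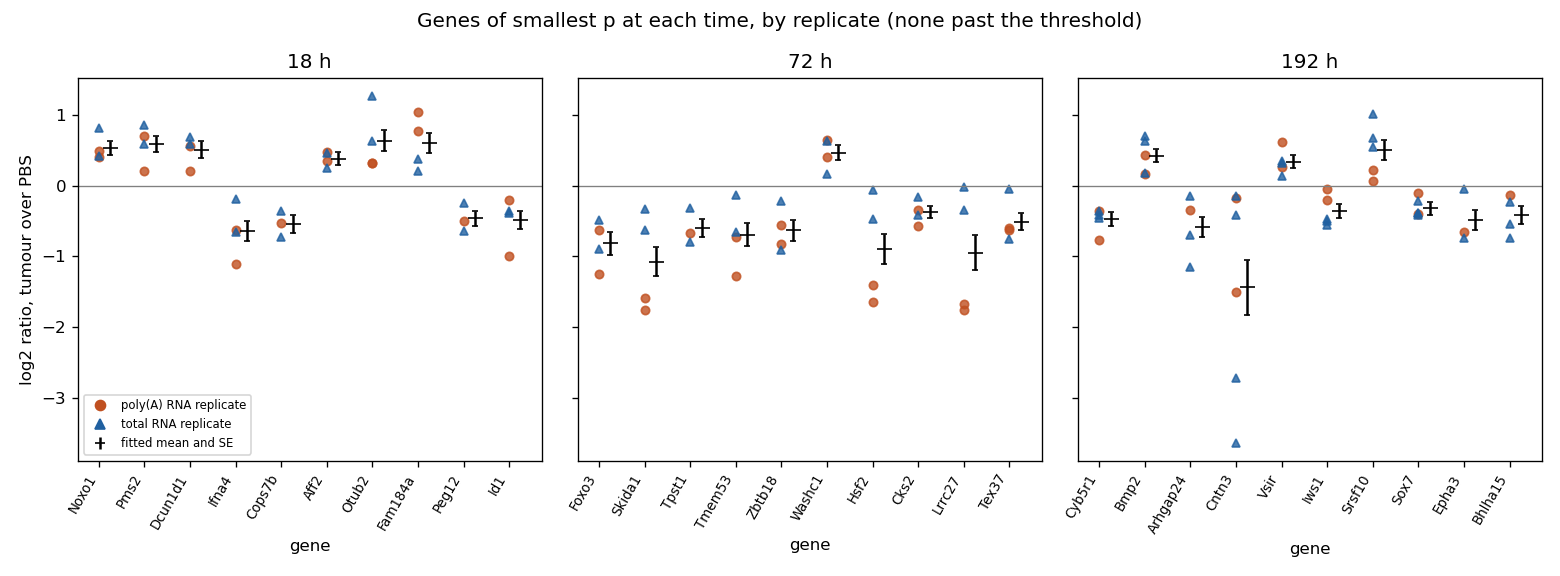
Log2 ratios of tumour over PBS (vertical axis) for 10 genes at each time (horizontal axis, 1 panel per time). These had the smallest p among genes with the same sign in every replicate that measured them, unnamed clones passed over. That the replicates of a gene share a sign follows from this choice and is no support for the gene. Points are replicates, circles for poly(A) RNA and triangles for total RNA, and the black mark is the fitted mean with its SE. No gene passed the adjusted test. Noxo1 at 18 h had a mean of 0.53 and Foxo3 at 72 h a mean of -0.81.

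The difference between times was tested for the same 6426 genes, and 0 passed in limma, with 321 at an unadjusted p under 0.05 (smallest adjusted p = 0.86). Noxo1 had the smallest p, at 0.53, 0.16 and -0.12 for 18, 72 and 192 h. Yap1, a transcriptional co-activator, stood at 0.47, -0.10 and -0.32, and Vsir at -0.21, -0.12 and 0.34. Tmem53 was at -0.016, -0.70 and 0.18, Depdc1a at 0.35, -0.32 and -0.35, and Zc2hc1b at 0.28, -0.37 and 0.22. With only the second scan Tmem53 at 192 h minus 72 h was -0.031, and in the authors' processed values Depdc1a at 18 h minus 192 h was -0.028. With only the poly(A) RNA replicates 9 genes passed, all 9 lowest at 72 h and among the 122 passing there. Of these 6 replicates 3 had 1 dye orientation only. Their 72 h arrays were all on layout 1, those of 192 h on layouts 2 and 3, and those of 18 h on layouts 1 and 3. Only 72 h had arrays with 6 files. Time is therefore mixed with orientation, layout and number of files.

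**Figure D2:**
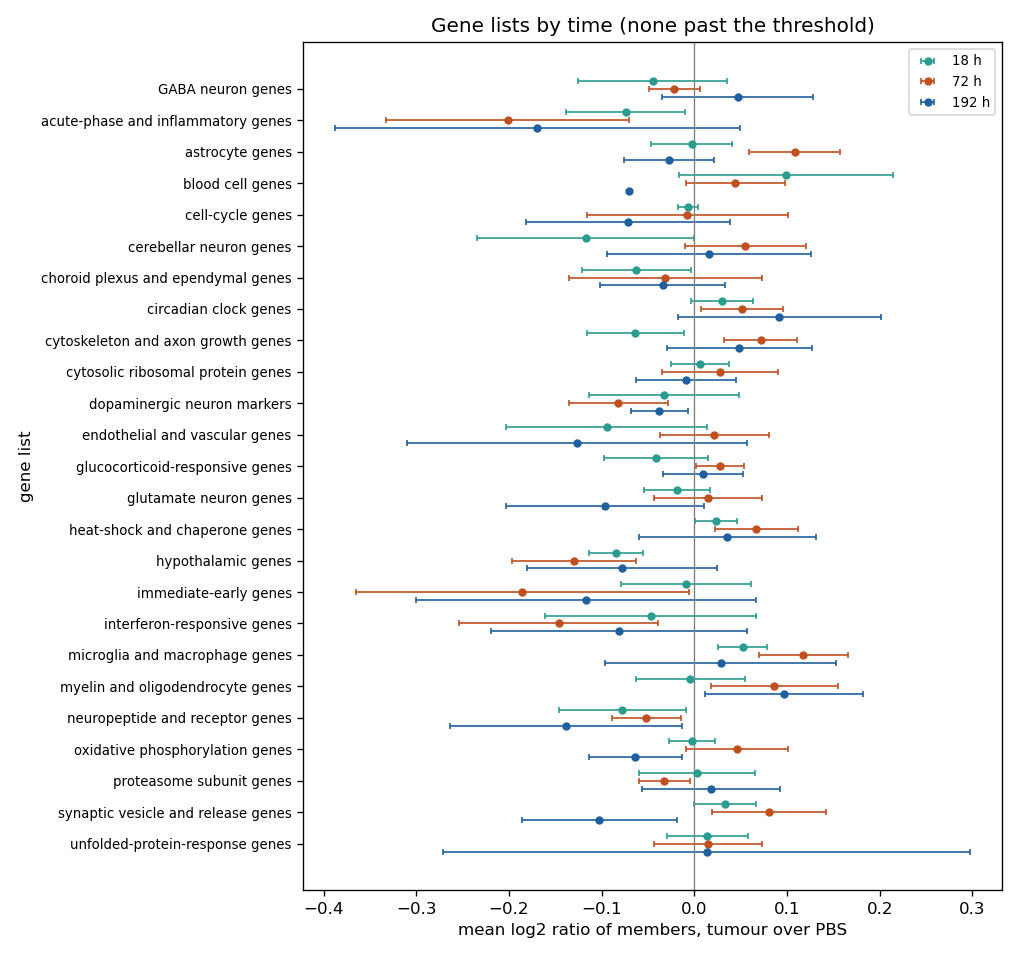
Mean log2 ratio of the members of each of the 25 tested gene lists (horizontal axis) at 18, 72 and 192 h, with the SE of the replicate means as bars. The cerebellar neuron genes at 18 h have a mean of -0.12 and the acute-phase genes at 192 h a mean of -0.17.

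Ratios of the opposite dye orientations of a replicate correlated below 0 in 10 of 11 replicates with both, with r from -0.55 to 0.25 and a median of -0.33 across genes, which are not independent replicates. The exception was 192 h replicate 4. All ratios here take the dyes as exchanged where the labels say so. Between replicates of 1 time the median r was 0.0075, and between replicates of different times 0.011. A dye effect, fitted as the difference between the orientations, passed for 349 genes, 5.43% of those tested in limma. If the dyes were not exchanged, this term would also hold any tumour effect.

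**Figure D3:**
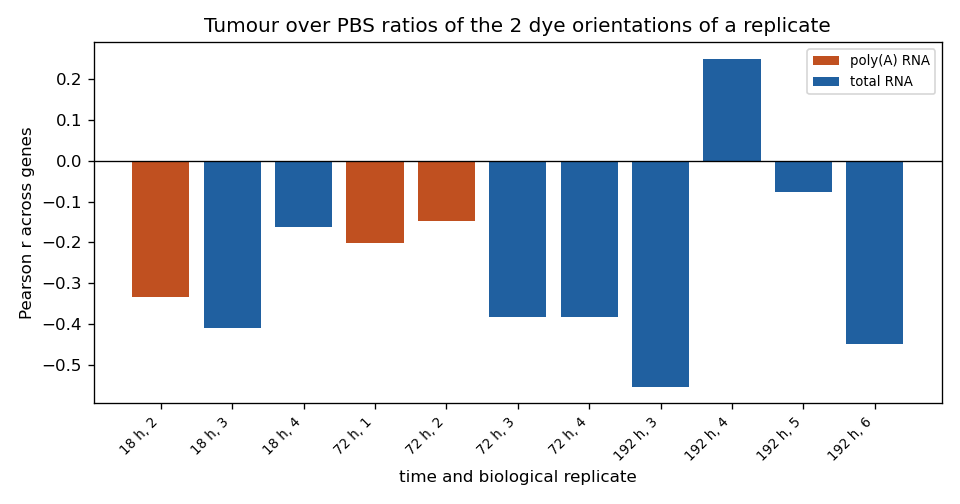
Pearson r across genes (vertical axis) between the tumour over PBS ratios of the opposite dye orientations, for each biological replicate that had both (horizontal axis). Bars below 0 mean that ratios tended to go opposite ways when the dyes were swapped. The values run from -0.55 to 0.25.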

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

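All results listed here are single replicates far from the others of their time, and no cause was tested for them. Of 73 groups tested 8 were marked, and chance marks about 1 in 20. Cyb5r1 at 192 h had a log2 ratio of -0.77 in replicate 1, against -0.46 to -0.36 in the others. Aif1 at 72 h was at 0.17 in replicate 1, against 0.50 to 0.54. Ndufa10 at 72 h was at -2.37 in replicate 1, against -0.16 to 0.049. Pmch at 72 h was at 0.040 in replicate 3, against -0.80 to -0.70. Lcn2 at 192 h was at 0.12 in replicate 2, against -0.33 to -0.30. Psmb3 at 192 h was at -5.07 in replicate 6, against -0.17 to 0.11. The mean of the oxidative phosphorylation genes at 72 h was 0.21 in replicate 2, against -0.024 to -0.0013. The mean of the acute-phase and inflammatory genes at 192 h was -1.36 in replicate 4, against -0.25 to 0.13. That replicate had a ratio for 2491 genes, the fewest of any.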

How the results depend on the processing

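The 77 results gave 1977 comparisons under 36 alternatives, 6 added after the data were seen. Of these 1937 were the same: 228 counts stayed 0 and the others kept their sign without passing. Another 28 reversed, 6 counts moved and 6 values passed. Gene and list values were over 1.5 times smaller or turned in 61 of 65 with the authors' processed values, 20 of 50 with only the second scan, 23 of 70 with print-tip loess, 21 of 70 without background subtraction, 13 of 40 in total RNA alone and 11 of 69 with the first 3 files. The authors' values had a median SD per array of 0.23, against 0.49 here. Their count of 61 therefore also holds this difference in scale and cannot be compared with the other counts. With normexp 33 of 70 were as much larger. No gene passed at 18 h or 192 h under any of the 33 settings run for it, where counts at an unadjusted p under 0.05 ran from 11 to 634 at 18 h and from 47 to 348 at 192 h. The settings tested unlike numbers of genes, and the 11 were of 579 genes, with only values measured in both orientations. At 72 h and between times, the poly(A) RNA replicates alone gave 122 and 9 genes and every other setting gave 0. The replicate block gave 0 genes differing between times (206 of 4160 at an unadjusted p under 0.05). Deviations from the mean of their time correlated at r = -0.15 to 0.11 between same-numbered replicates (median 0.080, against -0.030 for different numbers). Of 12 pairs 3 were over 0.1, so the number was not taken to pair them. Lists that passed were the ribosomal protein genes at 18 h and 192 h (mean 0.15 and 0.27), and oxidative phosphorylation (0.13), proteasome (0.14) and acute-phase genes (-0.25) at 192 h, all with median centring only, giving 1 and 4 lists. The acute-phase genes passed alone in total RNA (1 list, -0.32). The cerebellar neuron genes passed without 18 h replicate 3 (mean -0.21, and -0.028 without replicate 2), so with a replicate left out the number at 18 h ran from 0 to 1. Without loess, intensity-dependent dye differences stay in the ratios, and the cause was not tested. Only 5 lists had enough genes measured in every replicate for camera with an estimated correlation and for fry, and 0 passed in either.

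Reversed values follow, with no cause tested. With the authors' processed values, the acute-phase mean at 192 h was 0.0068, Tpst1 0.028, Tmem53 0.017, Zbtb18 0.054 and Ndufa10 0.0052 at 72 h, Ccl4 0.15, Lcn2 0.015, Il1b 0.048 and Il6 0.057 at 192 h, and Depdc1a at 18 h minus 192 h -0.028. With only the second scan, Tmem53 was 0.14 and Ndufa10 0.056 at 72 h, and Tmem53 at 192 h minus 72 h was -0.031. In total RNA the oxidative phosphorylation mean was -0.011, Hsp90b1 -0.041 and Ndufa10 0.026 at 72 h, and Pcp4 0.030 at 18 h. In poly(A) RNA at 192 h the acute-phase mean was 0.0062, Il1b 0.12, Psmb2 -0.014 and Psmb3 0.050. The proteasome mean at 192 h was -0.0012 without background subtraction and -0.0074 with array weights, and Sox7 was 0.11 with median centring only. With a replicate left out, the proteasome mean ran from -0.012 to 0.072, the oxidative phosphorylation mean at 72 h from -0.016 to 0.069 and Psmb3 from -1.04 to 0.00033. The median signal over background in the second scan was 1.69 and 2.49, and what it limits is untested.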

Other observations

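Dopaminergic neuron markers had mean log2 ratios of -0.032, -0.082 and -0.038 at 18, 72 and 192 h over 14 genes, and at 192 h 9 of the 14 were higher. Glucocorticoid-responsive genes were at -0.041, 0.027 and 0.0093 over 15 genes and myelin and oligodendrocyte genes at -0.0043, 0.086 and 0.097 over 11. Isg15, an interferon-induced ubiquitin-like gene, was at -0.36 at 192 h, lower in 6 of 6 replicates (adjusted p = 0.96 in limma). It is named after its value was seen. Of the 6 interferon-responsive genes tested, 3 were higher and 3 lower at 192 h (camera p = 0.29).

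Tests here were chosen after the result was seen, except the share of genes with the called sign in total RNA. Turning the sign of replicates in every combination gave 0 genes for the real signs and at most 0 for the others, with 8 of 8, 8 of 8 and 32 of 32 combinations as large at 18, 72 and 192 h. For lists the same numbers held (8, 8 and 32), and the highest other was 1, 0 and 2 against 0. At 18 and 72 h 8 combinations are too few for a share under 0.05. Between times all 100 assignments gave at least the real count of 0, with a highest other of 13. A real count of 0 fixes these outcomes, so they say nothing about chance. At an unadjusted p under 0.05, 26 of 32 combinations gave at least the 253 genes of 192 h (highest other 468). Between times 23 of 100 assignments gave at least 321 (highest other 717). At 18 and 72 h, 3 of 8 and 2 of 8 combinations gave at least the 347 and 596 genes (highest other 504 and 604). For none of these counts can chance be excluded.

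The 122 genes called at 72 h from poly(A) RNA replicates alone were 112 lower and 10 higher. Dye bias where a gene was not measured in both orientations may account for part of them, since 13.9% (8.33 to 21.4, exact binomial 95% interval) were measured in both orientations of both replicates, against 60.2% of tested genes. Extra scanner files may account for more: with only the first 3 files of each array 17 genes were called, 15 of them among the 122, of which 67 could be tested. Of a tumour effect shared with total RNA, the planned test decided nothing, as 52.1% (42.8 to 61.2) had the called sign there. In a test chosen after that outcome was seen, the median ratio in the called direction was 0.0076 (-0.019 to 0.030) against a median called size of 1.18. This would argue against an effect of at least 0.5 of that size, but only if the dyes were exchanged, so it stays open. Across genes, arrays of 1 orientation of the 2 poly(A) replicates correlated at r = 0.56 and 0.53 and arrays of opposite orientations at -0.15 and -0.22. Their agreement across genes thus went with the orientation. The arrays with tumour RNA in Cy5 were numbers 106, 107, 112 and 113, with 6 files each. Those with it in Cy3 were 197 and 199, with 3 files each. Orientation can therefore not be told apart from array number or number of files. The agreement was not tested on the 122. For these, a tumour effect in poly(A) RNA alone stays open too.

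Ratios of dye-swapped arrays of a replicate correlated below 0, and dye bias of single genes is a candidate explanation. Without turning signs, opposite arrays of different total RNA replicates correlated at a median r of 0.17. Dyes not exchanged on arrays recorded as swapped was tested first, and the median r within replicates (0.38) exceeded that between replicates by 0.21 (permutation p = 0.0019, two-sided, 10000 permutations), as that explanation predicts. A further test was then added, because dye bias shared by arrays with neighbouring numbers predicts the same: such arrays of different replicates correlated at a median r of 0.44 (6 pairs, numbers at most 5 apart), and the value within replicates minus this one was -0.056. These pairs came from 6 arrays of 3 of the 8 replicates, and within these 3 the median r was 0.38. Both therefore stay open, and a missing exchange cannot be told apart from shared dye bias with these arrays. Without an exchange, averaging the orientations would cancel a tumour effect in the 11 replicates with both, for genes measured in both. Per replicate these were a median of 58.6% of the tested genes. The counts of 0, the size test above and the simulated recovery therefore hold only if the dyes were exchanged. The same goes for reading the term that passed for 349 genes as a dye effect.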
